A study of Homo sapiens with 5 samples.

How the data were processed

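The analysis used 5 arrays of BJ human fibroblasts on the Affymetrix U133 Plus 2.0 design, 1 each from parental cells and from cells infected with retroviruses for GFP, MYOD1 wild type, MYOD1 L122R or MYC. Per the labels' protocols, infected cells were selected with zeocin and cells grew in medium with 10% serum. No label states whether the parental culture met zeocin. The deposited values are linear intensities, 1 per probe set and array. Per the submitters' processing notes they came from MAS5, but the values carry no sign of its background subtraction (the lowest values are 29 to 32) or of scaling to a common target (the 2% trimmed means are 87.4 for parental, 119.6 for GFP, 109 for MYOD1 wild type, 97.3 for MYOD1 L122R and 96.9 for MYC), so how they were summarized is open. Array images and probe-level files were not used here, and no detection calls were.

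From the deposited intensities, each array was rescaled to the same 2% trimmed mean (102.094), values under the 40th percentile of all values (48.4466, log2 5.60) were raised to it, and log2 levels were taken. Of 54675 probe sets, 62 are controls of the array, 41091 name a single gene, 1801 several genes and 11777 none. Of the single-gene probe sets 41037 were matched by gene ID. Each of 19775 genes was represented by its probe set with the highest mean level, and 16472 genes lay above the floor on at least 1 array. With 1 array per group no test and no p-value was computed. A gene was called at a difference of at least 2-fold if it lay above the floor on either array, and "at least" stands before a fold where the dimmer side was at the floor.

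Comparisons were each of MYOD1 wild type, MYOD1 L122R and MYC against GFP, MYOD1 L122R against MYOD1 wild type and against MYC, and GFP against parental. For 25 fixed gene lists, 730 distinct genes of which 677 had a level and 638 lay above the floor, the median log2 difference of members above the floor was placed among medians of 10000 random lists (seed 20) of the same size drawn from 20 bins of level. The lists cover myogenic transcription factors and cofactors, sarcomere, excitation-contraction coupling and neuromuscular junction, muscle energy metabolism, Notch and ID genes, MYC targets in 3 classes, genes reported as repressed by MYC, glycolysis, cell cycle, cell cycle inhibitors with D cyclins and their kinases, p53 targets, fibroblast and extracellular matrix, smooth muscle, interferon response, inflammatory genes, growth factor and PI3K signalling, the unfolded protein and ATF4 response, cholesterol synthesis, and markers of 5 other cell types. Of the members, 20 sit in more than 1 list and 53 have no single-gene probe set here. The Notch and ID list also holds other genes listed as inhibitors of myogenesis, such as those of the TWIST, SNAI and ZEB families. Resemblance was read from genes called on one array against GFP and measured on another against parental, from correlations of differences across genes, and from shared calls. The last 2 were set beside 100 simulations of unchanged arrays built from the GFP and parental difference.

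Genes named in the text are the 10 largest and 10 lowest differences of each main comparison that also passed 2-fold against parental, the 10 largest and 10 lowest of MYOD1 L122R against MYOD1 wild type, the 5 largest and 5 lowest of the other comparisons, the 3 largest and 3 lowest of each list, and the introduced genes. This rule, the groups, the comparisons, the main settings and the first set of alternatives were written before the data were examined. MYOG, IGDCC4, ADGRE2, GASK1B and FERMT1 fall outside the rule and were named after their values were seen. That set held quantile normalization, values as deposited, floors at the 20th and 60th percentiles, the median of all probe sets of a gene, leaving out shared-sequence probe sets (names ending in x_at or s_at), the other control array, and split controls. Normexp background correction (offset 50), local median centring by level (window 2001), lists without genes shared between them, and the mean of GFP and parental as control were chosen after the data were seen.

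The procedure was tested on simulated data, with 200 of 19775 genes changed on a simulated array set against GFP. The change acted on the signal above an assumed background. The 200 genes were drawn only from those more than 2-fold above the floor on GFP, so recovery nearer the floor was not measured. At 2-fold, 32% of genes made higher and 28% of genes made lower passed the size rule, at 3-fold 100% and 72%, and at 4-fold 100% and 96%. Of 19575 unchanged genes 48 passed. The noise was drawn from the GFP and parental difference, so this last count restates the spread between those arrays. A recovered 8-fold change measured 2.89 for genes made higher and 2.09 for genes made lower. The SD of the log2 difference between GFP and parental was 0.23. Tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.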

Results

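The series held 5 expression arrays of BJ cells, an established line of human skin fibroblasts, with 1 array for each of 5 cultures. The parental culture was left uninfected. The other cultures had taken up a retrovirus carrying GFP (a fluorescent protein that serves as control), wild type MYOD1, the MYOD1 substitution L122R or MYC, and had been kept in zeocin at 500 µg/ml for 1 week. MYOD1 is the basic helix-loop-helix factor that can turn fibroblasts toward skeletal muscle, L122R puts an arginine in place of a leucine in its DNA-binding region, and MYC is a growth-promoting factor of the same protein class. The design asks how each profile differed from that of GFP, and whether L122R resembled wild type MYOD1 or MYC. Each array read 54675 probe sets, of which 52.4% (GFP) to 69.9% (parental) lay above the floor after rescaling. With 1 array per group there was no replicate check on any difference and no test, and the number of arrays limits the precision. Gene differences are log2 values after rescaling and flooring, and a list's percentile places its median among 10000 random lists of matched level, as a description of these arrays.

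MYOD1 lay near the floor of 48.4 on every array, with a scaled intensity of 57.9 on the array labelled MYOD1 wild type, 44.1 on the array labelled MYOD1 L122R, 44.4 on GFP, 52.6 on parental and 54.8 on the array labelled MYC. MYC was dimmer on the array labelled MYC (220) than on GFP (328) or parental (334), a log2 difference of −0.58 from GFP. It was 202 on the array labelled MYOD1 wild type (−0.70) and 168 on the array labelled MYOD1 L122R (−0.97). The MYC signal thus goes against its label, and the MYOD1 signal does not separate the MYOD1 arrays from the others. Each gene had 1 probe set here, and whether it reads the introduced copy is not known, so arrays are called by their labels and every direction below rests on those labels. MYOG (myogenin, a muscle regulator that MYOD1 activates) was 105 on the array labelled MYOD1 wild type against 54.7 on GFP, a log2 difference of 0.94, and 55.6 on the array labelled MYOD1 L122R.

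**Figure D1:**
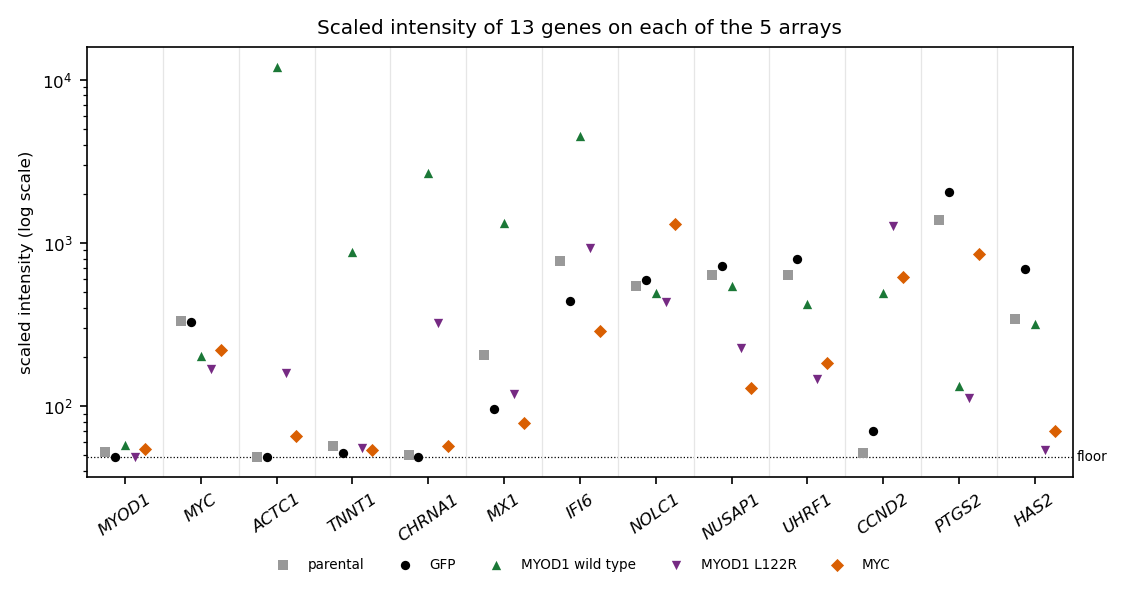
Scaled intensity (log axis) of 13 genes, with 1 symbol per array and the floor as a dotted line. MYC lies below its GFP value on the 3 arrays labelled MYOD1 wild type, MYOD1 L122R and MYC, while ACTC1 reaches 12016 on the array labelled MYOD1 wild type and sits at the floor on GFP.

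GFP against parental compares 2 cultures without MYOD1 or MYC and gauges the differences seen between control arrays. The chemokines CXCL8 (2.25) and CXCL1 (1.81), the cytokine receptor IL13RA2 (1.74), the growth factor EREG (1.66) and ID1 (1.70), an inhibitor of helix-loop-helix factors, were higher with GFP. The growth factor binding protein IGFBP3 (−1.81), the sulfatase SULF1 (−1.72), the matrix protein POSTN (−1.65), the microtubule regulator STMN2 (−1.56) and the stress protein NUPR1 (−1.39) were lower. In all, 26 genes were at least 2-fold higher and 18 at least 2-fold lower, 0.275% of the 15992 genes above the floor on either array. Of 33 inflammatory and senescence-associated secretory genes 6 were higher and 2 lower (median 0.18, percentile 100). The medians of the interferon response list (−0.37), of the fibroblast and extracellular matrix list (−0.30) and of the cholesterol synthesis list (−0.20) all lay at percentile 0. Genes reported as repressed by MYC (−0.10, percentile 0.11), the unfolded protein and ATF4 list (−0.04, percentile 0.39) and cell cycle genes (−0.01, percentile 0.69) lay low too, each inside the random range in some alternatives. List medians outside the central 95% thus also arose between the control arrays. ID2 and ID3, close relatives of ID1, were higher as well (1.12 and 1.39). Without rescaling, the whole GFP array lay above parental by a median of 0.35 and 98.4% of calls were higher, against 59.1% after rescaling (38.3% with quantile normalization, 40% with centring by level). NUPR1 was under 2-fold without rescaling, and POSTN, EREG and ID2 were under 2-fold by the median of all their probe sets.

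On the array labelled MYOD1 wild type, genes of skeletal muscle were far above their GFP levels. ACTC1, the cardiac actin that developing skeletal muscle also makes, was at least 248-fold higher, at 12016 against the floor. CHRNA1, a subunit of the muscle acetylcholine receptor, was at least 55.0-fold higher, and KLHL41, a kelch protein of the sarcomere, at least 24.4-fold. TNNT1, slow skeletal troponin T, was higher by 4.10 and HSPB3, a small heat shock protein of muscle, by 3.96. Of 38 sarcomere genes above the floor on any array 16 were at least 2-fold higher and 0 lower, with a list median of 0.75. Of 25 genes in the muscle energy metabolism list 13 were higher and 0 lower, with a median of 1.12. That list also holds KLHL41, HSPB3 and other muscle proteins outside energy metabolism, so its counts do not measure metabolism alone. Of 30 genes of excitation-contraction coupling and the neuromuscular junction 9 were higher and 0 lower (median 0.19), among them ITGA7 (2.42), the laminin receptor of muscle, and DYSF (2.23), a membrane repair protein. Among 21 myogenic transcription factors and cofactors 5 were higher and 0 lower (median 0.32), led by MEF2C (2.77) and RBM24 (1.82). The Notch and ID list, meant to cover inhibitors of myogenesis, had 5 higher and 0 lower of 22 (median 0.22). Among them DLL1 was at least 7.501-fold and HEYL at least 6.96-fold higher, and HEY1 was higher by 2.33. That list also holds genes such as SNAI2, so its counts do not measure Notch and ID genes alone. The medians of the first 4 of these lists lay at percentile 100 and that of the Notch and ID list at percentile 99.97.

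Interferon response genes formed the other large group on that array. Of 37 members 30 were at least 2-fold higher than on GFP and 0 lower, with a median of 1.95 (percentile 100). MX1, an antiviral GTPase, was higher by 3.80, IFI27 by 3.72 and IFI6 by 3.36, while the chemokine CXCL10 stayed at the floor and ISG20 (0.67) and IFITM2 (0.89) were within 2-fold. On the arrays labelled MYOD1 L122R and MYC the same list had 2 and 0 members higher.

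Further genes far above GFP on the array labelled MYOD1 wild type were the secreted LRRC17 (4.99), SERPINF1 (4.04) and RARRES2 (at least 14.2-fold), and the basement membrane collagen COL15A1 (3.89). Far below lay PTGS2 (−3.93), the inducible prostaglandin synthase, the guidance cue SLIT2 (−2.68), the Wnt antagonist SFRP1 (−2.65), the keratin KRT19 (−2.55), the keratin-associated KRTAP1-5 (−2.45), and SPHKAP (−2.34). CHRNA1 was 3.70, LRRC17 2.65 and KRT19 −1.27 by the median of all probe sets. SCUBE3 (−2.68), CLDN11 (−2.40), HMGA2 (−2.26) and F2R (−2.31) belong to the lowest 10 as well, but depend on the choice of probe set: SCUBE3, CLDN11 and HMGA2 were within 2-fold by the median of all probe sets (−0.47, −0.06 and −0.40) and F2R without shared-sequence probe sets (−0.03). Of 45 fibroblast and extracellular matrix genes 8 were higher, led by the thrombospondin THBS2 (2.13), and 8 lower, led by the fibulin FBLN1 (−2.04), and the list median of −0.14 (percentile 0.68) was 0.06 without shared-sequence probe sets. Inflammatory genes had 2 higher and 7 lower of 33 (median −0.30, percentile 0), MMP1 at −1.81 among them, but the median was −0.04 against parental. Of 50 cell cycle genes 0 were higher and 1 lower (median −0.24, percentile 0.01), and of 16 smooth muscle genes 1 was higher, SYNPO2 (2.38), and 1 lower (median −0.24, percentile 0.23, inside the random range for some choices of probe sets). Among MYC targets, 0 of 35 ribosome biogenesis genes passed 2-fold (median −0.17, percentile 1.5, inside the random range against parental), 1 of 36 nucleotide, polyamine and mitochondrial genes did, the spermidine synthase SRM (−1.07, under 2-fold against parental; list median −0.15, inside the random range in several alternatives), and 0 of 27 translation genes (median −0.08).

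Across all genes, 372 were at least 2-fold higher and 203 at least 2-fold lower on the array labelled MYOD1 wild type than on GFP, and 297 and 102 of them were so against parental too. At 4-fold the counts were 107 and 20. By the median of all probe sets 252 genes were higher and 121 lower, and without rescaling the share of calls that were higher was 52.98% in place of 64.7%.

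On the array labelled MYOD1 L122R, the genes furthest above GFP were of classes other than skeletal muscle. NEFL, the neurofilament light chain of neurons, was at least 24.6-fold higher, DNAJC12, a cochaperone of aromatic amino acid hydroxylases, was higher by 4.60, and CH25H, cholesterol 25-hydroxylase, was at least 21.3-fold higher. ASS1, argininosuccinate synthase, was 6151 against 342 on GFP (4.17), the water channel AQP3 was at least 17.5-fold higher, and LRRC17 (4.08), LRRN4CL (3.996) and OLFML2A (at least 11.4-fold) followed. AQP3 was 1.22 and LRRC17 2.19 by the median of all probe sets. At their brightest probe sets CCND2, cyclin D2, was higher by 4.18 and TTYH2 by 3.81. CCND2 was 0.97 by the median of all probe sets and TTYH2 0.30 without shared-sequence probe sets. Several of these genes, at the same probe sets, were higher on the array labelled MYOD1 wild type too. They were LRRC17 (4.99), AQP3 (3.66), LRRN4CL (3.13), CCND2 (2.81), OLFML2A (2.57) and ASS1 (2.33). NEFL, DNAJC12, CH25H and TTYH2 were within 2-fold of GFP there. Lowest were PTGS2 (−4.18), the hyaluronan synthase HAS2 (−3.69), the Wnt antagonist DKK1 (−3.64), KRT19 (−3.06), GPRC5A (−2.80), the cadherin CDH2 (−2.67), SERPINB7 (−2.51), UHRF1 (−2.44), which maintains DNA methylation at replication, and the growth factor FGF2 (−2.42). KRT19 was −1.53 by the median of all probe sets, and GPRC5A and FGF2 were −1.78 and −1.61 against parental. PDGFRA, a growth factor receptor of fibroblasts, was −2.59 at its brightest probe set and −0.36 by the median of all.

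Cell cycle genes were lower as a group on the array labelled MYOD1 L122R. Of 50 members 26 were at least 2-fold lower and 0 higher (median −1.05, percentile 0), such as NUSAP1, a spindle protein (−1.66), and RRM2, a subunit of ribonucleotide reductase (−1.62), while CCNE1 (0.21) and CENPF (−0.05) were near GFP. The 3′/5′ signal ratio of ACTB, a sign of RNA integrity, was 3.98 on this array, 3.23 on GFP and 4.34 on parental, and that of GAPDH 1.30, 1.21 and 1.34. Smooth muscle genes had 3 lower and 0 higher of 16 (median −0.41, percentile 0, inside the random range at −0.17 without shared-sequence probe sets), CCN2 at −1.46 among them. Cholesterol synthesis genes had 4 lower and 0 higher of 18 (median −0.34, percentile 0.05), led by MSMO1 (−1.55) and the transport protein STARD4 (−1.35).

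Few muscle genes were higher on the array labelled MYOD1 L122R. In the sarcomere list 1 of 38 genes was higher, ACTC1 (at least 3.27-fold), and 0 lower (median 0.00). In the muscle energy metabolism list 1 of 25 was higher, KLHL41 (at least 2.17-fold, and under 2-fold in 3 of the alternatives), with a median of 0.00. Both medians are 0.00 because many members sat at the floor on both arrays, where no difference can be seen. Above 0 were 14 sarcomere members and 12 of the energy metabolism list, and below 0 were 7 and 5. In the excitation-contraction and neuromuscular list 3 of 30 were higher (median 0.06): CHRNA1 (at least 6.63-fold), the junctional protein JPH1 (at least 4.94-fold) and the muscle cadherin CDH15 (2.12). CHRNA1 was 1.46 and JPH1 1.15 by the median of all probe sets. All 3 medians lay inside the central 95% of random lists, though without rescaling those of the energy metabolism list (0.00) and of the excitation-contraction and neuromuscular list (−0.11) lay at percentiles 99.995 and 99.6, where the median of all genes was −0.23. The list of myogenic transcription factors and cofactors had 3 higher and 1 lower of 21 (median 0.16, percentile 99.045), and the median was −0.05 against parental. Among the higher was MSC, a repressor of myogenesis (1.25, under 2-fold without rescaling), and the lower was RBM24 (−1.10, under 2-fold against parental). This list thus mixes genes that promote and genes that hold back myogenesis. Its counts, here and in the other comparisons, therefore do not measure myogenic activity. The Notch and ID list had 2 higher and 0 lower of 22 (median 0.29, percentile 100), with the ligand JAG1 at 1.67 (0.45 by the median of all probe sets). The lists of MYC targets did not stand apart: 0 of 35 ribosome biogenesis genes passed 2-fold (median −0.05, percentile 47.4), 0 were higher and 1 lower of 36 nucleotide, polyamine and mitochondrial genes (median −0.03, percentile 55.4), and 1 was higher and 0 lower of 27 translation genes (median −0.07, percentile 38.7). Of genes reported as repressed by MYC 3 were higher and 4 lower of 27 (median −0.07, percentile 23.7), and the median lay outside the random range against parental (−0.16, percentile 0.67), without shared-sequence probe sets (−0.17, percentile 0.52) and without genes of other lists (−0.26, percentile 1).

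Of 37 interferon response genes 2 were higher on the array labelled MYOD1 L122R (median 0.16, percentile 99.8), a median that was −0.09 against parental. Inflammatory genes had 2 higher and 7 lower of 33 (median −0.09, percentile 2.52), and matrix genes 3 higher and 9 lower of 45 (median −0.07, percentile 35.1, but −0.41 and percentile 0 against parental), with FBLN1 at −2.20. Across all genes 323 were at least 2-fold higher than on GFP and 302 at least 2-fold lower, 248 and 182 of them against parental too, and 54 and 24 passed 4-fold. By the median of all probe sets the counts were 185 and 192, and without rescaling 190 and 674, with 22.0% of calls higher in place of 51.7%.

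**Figure D2:**
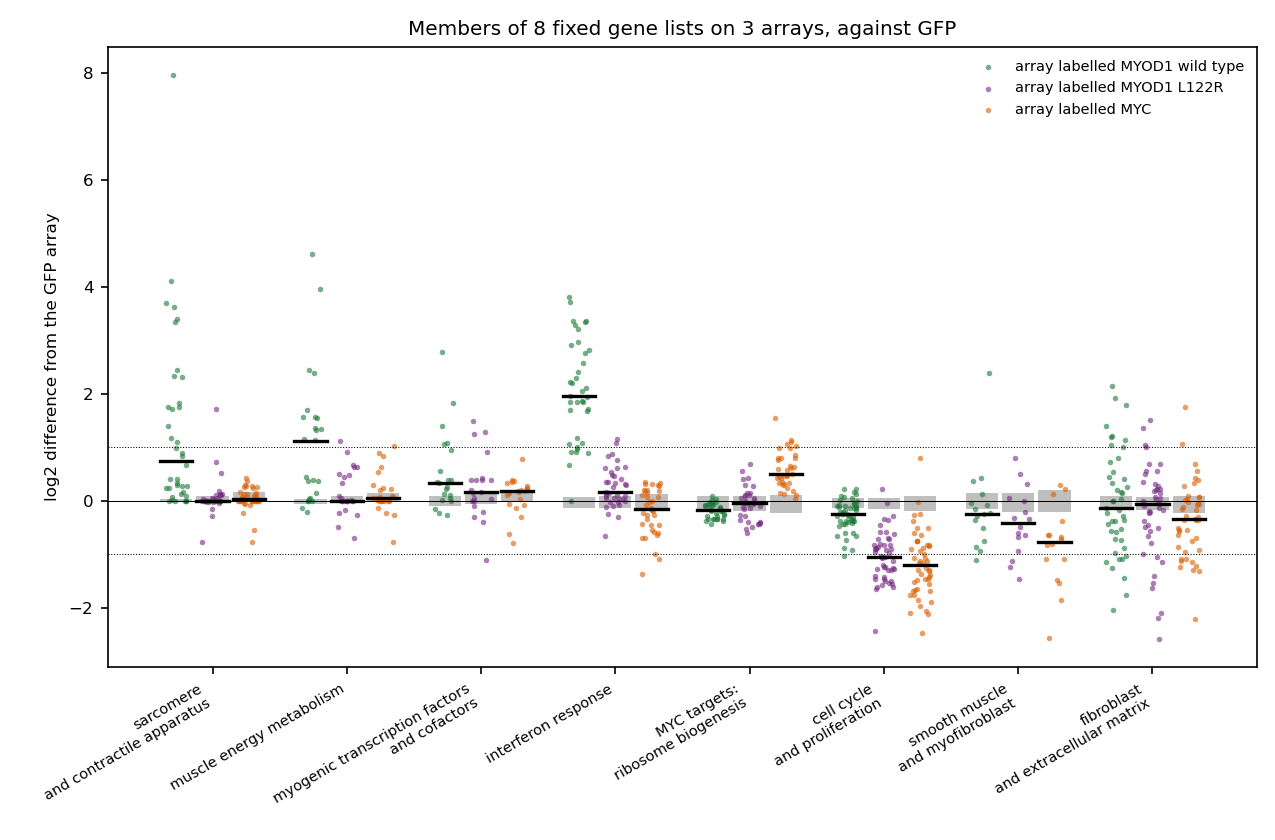
Log2 difference from GFP (vertical axis) of each member above the floor of 8 fixed lists, for the arrays labelled MYOD1 wild type, MYOD1 L122R and MYC. Points are genes, black bars list medians, grey boxes the central 95% of medians of random lists and dotted lines 2-fold; the interferon median is 1.95 on the array labelled MYOD1 wild type, and the cell cycle medians are −1.05 and −1.21 on the arrays labelled MYOD1 L122R and MYC.

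On the array labelled MYC, where the MYC probe set itself was dimmer than on GFP, the lists of MYC targets were higher by small amounts. Of 35 ribosome biogenesis genes 5 were at least 2-fold higher and 0 lower (median 0.50, percentile 100), with the nucleolar proteins NOLC1 (1.14) and LYAR (1.09) among them. Of 36 nucleotide, polyamine, one-carbon and mitochondrial genes 1 was higher, the chaperonin HSPD1 (1.10), and 1 lower, the thymidylate synthase TYMS (−1.61), with a median of 0.52 (percentile 100). Of 27 translation genes 2 were higher, PUS7 (1.54), a pseudouridine synthase, and EXOSC5 (1.02), and 0 lower (median 0.26, percentile 99.99). Without rescaling, which shifts all genes of an array alike, this median was −0.05, at percentile 99.98. NOLC1, LYAR, HSPD1 and EXOSC5 were under 2-fold without rescaling. Genes reported as repressed by MYC had 2 higher and 6 lower of 27 (median −0.28, percentile 0.31), among them the matricellular CCN1 (−1.49) and the transcription factor KLF6 (−1.25, under 2-fold against parental). Between GFP and parental this list's median was −0.10, at percentile 0.11.

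The cell cycle list was lower on the array labelled MYC as well. Of 50 members 32 were at least 2-fold lower and 0 higher (median −1.21, percentile 0), led by NUSAP1 (−2.48), UHRF1 (−2.12) and the thymidine kinase TK1 (−2.11), while CCNE1, cyclin E1, was 0.79. Outside the list, the division genes CEP55 (−2.52), CDKN3 (−2.22), DIAPH3 (−2.18) and ANLN (−2.18) were among the 10 lowest, DIAPH3 at −1.12 by the median of all probe sets. On this array the 3′/5′ ratio was 5.37 for ACTB, the highest of the 5, and 1.29 for GAPDH, between GFP (1.21) and parental (1.34), and the poly-A control probe sets were 1.03 above GFP. Of 16 smooth muscle genes 6 were lower and 0 higher (median −0.77, percentile 0), with the focal adhesion protein TGFB1I1 at −1.85. TAGLN, transgelin, was −2.57 at its brightest probe set and 0.04 without shared-sequence probe sets. Matrix genes had 2 higher and 9 lower of 45 (median −0.35, percentile 0.04), and inflammatory genes 0 higher and 8 lower of 33 (median −0.43, percentile 0, but −0.12 and inside the random range against parental), with the chemokine CXCL12 at −2.51 (−1.68 by the median of all probe sets) and IGFBP5 at −2.06.

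Single genes furthest above GFP on the array labelled MYC were DNAJC12 (3.03), the mitochondrial adenylate kinase AK4 (2.80), the cytochrome P450 CYP1B1 (2.68), the neuropeptide GAL (2.62), SERPINF1 (2.42), ASS1 (2.13) and NEFL (at least 4.41-fold). CCND2 (3.13), the amino acid transporter SLC6A15 (2.37) and TTYH2 (2.15) belong to the top 10 too, but were 0.60, 0.50 and 0.20 under the least favourable choice of probe sets. AK4 was 1.64, GAL 1.38 and NEFL 1.38 by the median of all probe sets. HAS2 (−3.29) was the lowest. CEMIP, which degrades hyaluronan, was −2.92 and PDGFRA −2.22 at their brightest probe sets, against −0.13 and −0.27 under the least favourable choice. Muscle lists held few calls: 0 of 38 sarcomere genes passed 2-fold (median 0.03), 0 of 30 in the excitation-contraction and neuromuscular list (median 0.11) and 0 of 21 myogenic factors (median 0.17). In the Notch and ID list 0 of 22 did (median 0.09, but −0.16 and percentile 1.45 with the floor at the 60th percentile). In the energy metabolism list 1 of 25 did, the phosphofructokinase PFKM (1.02, under 2-fold without rescaling, list median 0.04). Of 37 interferon response genes 0 were higher and 2 lower (median −0.16, percentile 1.70, inside the random range without shared-sequence probe sets and after normexp correction), IFIT3 lowest at −1.38. Across all genes 194 were at least 2-fold higher than on GFP and 374 at least 2-fold lower, 149 and 237 of them against parental too, and 12 and 18 passed 4-fold. By the median of all probe sets 102 genes were higher and 250 lower, and normexp background correction gave a count of higher genes between 102 and 194. Without rescaling the counts were 73 and 830, with 8.08% of calls higher in place of 34.2%.

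Between the arrays labelled MYOD1 L122R and MYOD1 wild type, muscle and interferon genes were lower with L122R. ACTC1 was lower by a log2 difference of −6.24, TNNT1 −3.98, KLHL41 −3.49, HSPB3 −3.49 and the myosin light chain MYL11 −3.36, while the slow troponins TNNI1 and TNNC1 were at least 12.3-fold and at least 10.1-fold lower. Sarcomere genes had 19 lower and 0 higher of 38 (median −0.83), and the muscle energy metabolism list 10 lower and 0 higher of 25 (median −0.88). The excitation-contraction and neuromuscular list had 8 lower and 1 higher, JPH1 (at least 4.94-fold), of 30 (median −0.11). Interferon response genes had 28 lower and 0 higher of 37 (median −1.81), with MX1 at −3.49 and IFIT1 at −3.29. Cell cycle genes had 17 lower and 0 higher of 50 (median −0.83), with KIF20A at −1.63 and TOP2A at −1.52. All 5 of these medians lay at percentile 0. The 3′/5′ ratio of ACTB was 3.98 with L122R and 3.16 with wild type, and that of GAPDH 1.30 and 1.21. Cholesterol synthesis genes had 4 lower and 0 higher of 18 (median −0.35, percentile 0.04). Genes higher with L122R were DNAJC12 (at least 24.8-fold), NEFL (4.59), CH25H (3.62), the Wnt inhibitor APCDD1 (3.15), WFDC1 (3.14), the protocadherin DCHS1 (3.01), the leukotriene hydrolase LTA4H (2.77) and SLC43A3 (2.60). LAMA4 (2.74), TTYH2 (3.57) and PDLIM3 (−3.68) were under 2-fold for some choices of probe sets, and COL15A1 was −3.89. APCDD1 was 1.65 by the median of all probe sets and DCHS1 1.11 without shared-sequence probe sets.

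Of the remaining lists in this comparison, myogenic transcription factors and cofactors had 1 higher and 3 lower of 21 (median −0.01, percentile 15.5). RBM24 was −2.92 and MEF2C −1.87. The Notch and ID list had 1 higher and 3 lower of 22 (median −0.07, percentile 7.40), with HEY1 at −2.02. MYC targets passed 2-fold in 0 of 35 ribosome biogenesis genes (median 0.12, percentile 98.3), in 1 of 36 nucleotide, polyamine and mitochondrial genes, TYMS, lower (median 0.15, percentile 99.9), and in 2 of 27 translation genes, PUS7 and EIF4EBP1, higher (median −0.03, percentile 56.7). The ribosome median was inside the random range after quantile normalization and the nucleotide median without shared-sequence probe sets. Matrix genes had 5 higher, such as THY1 (1.54), and 7 lower, such as the proteoglycans DCN (−2.41) and LUM (−2.14), of 45. Their median was −0.16 (percentile 2.38, inside the random range in 7 of 9 alternatives). The unfolded protein and ATF4 list had a median of −0.26 (percentile 0.15, inside in 1 of 9). Genes reported as repressed by MYC had −0.19 (percentile 0.76, inside in 5 of 9), and neural markers −0.04 (percentile 1.955, inside in 3 of 9). In all, 313 genes were higher and 403 lower, 39 and 77 at 4-fold. By the median of all probe sets 169 were higher and 281 lower. Without rescaling 29.1% of calls were higher in place of 43.7%.

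Between the arrays labelled MYOD1 L122R and MYC, the MYC target lists were lower with L122R. Ribosome biogenesis genes had 6 lower and 0 higher of 35 (median −0.62), with NOLC1 at −1.57 and the nucleolar methyltransferase FBL at −1.49. The nucleotide, polyamine and mitochondrial list had 1 lower and 0 higher of 36 (median −0.48) and the translation list 1 lower, IARS1 (−1.22), and 0 higher of 27 (median −0.34), all 3 at percentile 0. Cell cycle genes had 0 members past 2-fold of 50 (median 0.16, percentile 99.6, inside the random range without shared-sequence probe sets). Interferon genes had 5 higher and 0 lower of 37 (median 0.43, percentile 100), with IFI6 at 1.69, and the Notch and ID list 3 higher and 0 lower of 22 (median 0.33, percentile 100), with SNAI2 at 1.28. Myogenic transcription factors had 1 higher and 0 lower of 21 (median 0.16, percentile 99.9, inside the random range for some choices of probe sets). The other muscle lists held few calls and had medians of 0.00: 1 of 38 sarcomere genes was higher, ACTC1 at 1.28 (percentile 97.7, inside the random range in 7 of 9 alternatives), 3 of 30 genes of the excitation-contraction and neuromuscular list, CHRNA1 at 2.498 and CDH15 at 1.57 among them (percentile 96.9), and in the energy metabolism list 1 was higher and 1 lower of 25 (percentile 83.4). Cholesterol synthesis genes had 3 lower and 0 higher of 18 (median −0.33, percentile 0.02), with DHCR7, the last enzyme of the pathway, at −1.92. CH25H (3.09), LRRN4CL (3.09), APCDD1 (2.88), LRRC17 (2.79) and SHISA2 (at least 6.98-fold) were highest with L122R, and PTGS2 (−2.93), GAL (−2.496), the glycogen phosphorylase PYGL (−2.44) and CYP1B1 (−2.30) lowest. By the median of all probe sets CHRNA1 was 1.35, APCDD1 1.46, LRRC17 1.55 and GAL −1.32, and the desaturase SCD (−2.80) was under 2-fold. In all, 322 genes were higher and 193 lower, 38 and 10 at 4-fold, against 182 and 107 by the median of all probe sets.

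To ask which profile L122R resembled, genes chosen on one array against GFP were read on the other against parental, so that no array entered both steps. The 372 genes higher with wild type MYOD1 had a median of 0.15 on the array labelled MYOD1 L122R (percentile 100), where 72 of them (19.4%) were at least 2-fold higher and 12 lower, and the 203 lower genes had a median of −0.48 (percentile 0), with 53 (26.1%) at least 2-fold lower. The 194 genes higher on the array labelled MYC had a median of 0.44 (percentile 100), with 50 (25.8%) at least 2-fold higher, and the 374 lower genes had a median of −0.74 (percentile 0), with 131 at least 2-fold lower and 1 higher. Read on the array labelled MYOD1 wild type, the same 194 and 374 MYC genes had medians of 0.03 (percentile 98.6) and −0.19 (percentile 0), with 17 and 40 past 2-fold in the same direction, and the first of these medians was −0.06 with the controls exchanged.

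Across 16472 genes, which are not independent replicates, differences from GFP on the arrays labelled MYOD1 L122R and MYC had a Pearson correlation of 0.56, those of MYOD1 L122R and MYOD1 wild type 0.44, and those of MYOD1 wild type and MYC 0.23. Unchanged arrays simulated from the GFP and parental difference gave 0.50. That value follows from sharing the GFP array with equal noise on each array, whatever the data, so it does not gauge resemblance. The covariances of 0.0942, 0.0783 and 0.0388 exceeded the simulated 0.0191 by 0.0750, 0.0591 and 0.0197. The simulated covariance assumes equal noise as well, so these excesses may hold more of the shared GFP array than it allows for. With the first array set against GFP and the second against parental the correlations were 0.39, 0.29 and 0.05. The covariances were then 0.0654, 0.0495 and 0.00884, or 0.0688, 0.0483 and 0.0135 with the controls exchanged. Of the lower genes, 165 were shared by the arrays labelled MYOD1 L122R and MYC, against 6.86 for independent lists and 4.71 for simulated unchanged arrays, and 121 with split controls. Of the higher genes 46 were shared by that pair (3.80 independent, 40 with split controls). MYOD1 L122R and MYOD1 wild type shared 86 higher genes (7.29 independent, 79 with split controls) and 92 lower genes (3.72 independent, 64 with split controls), and MYOD1 wild type and MYC shared 15 higher genes (4.38 independent, 15 with split controls) and 61 lower genes (4.61 independent, 35 with split controls). Counts without split controls share the GFP array on both sides. The arrays labelled MYOD1 L122R and MYC also departed from GFP in technical measures, where MYOD1 wild type lay near GFP. Poly-A control probe sets were 0.35 and 1.03 above GFP on these arrays (wild type −0.002, parental −0.04). The ACTB 3′/5′ ratio was 3.98 and 5.37 (GFP 3.23, wild type 3.16, parental 4.34). Whether these departures contribute to the resemblance was not tested.

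Past 2-fold against both controls, 10 genes were higher on all 3 arrays: CCND2, ASS1, AQP3, LRRC17, SERPINF1, IGDCC4, ADGRE2, GASK1B, FERMT1 and CDK6. By the median of all probe sets 3 of them stayed so, ASS1, SERPINF1 and IGDCC4, and ASS1 and SERPINF1 did under every alternative that kept a probe set of theirs. A further 46 were higher on both MYOD1 arrays, 21 on those labelled MYOD1 L122R and MYC and 1 on those labelled MYOD1 wild type and MYC. Of lower genes 15 were shared by all 3 arrays, 24 by both MYOD1 arrays, 81 by those labelled MYOD1 L122R and MYC and 10 by those labelled MYOD1 wild type and MYC.

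**Figure D3:**
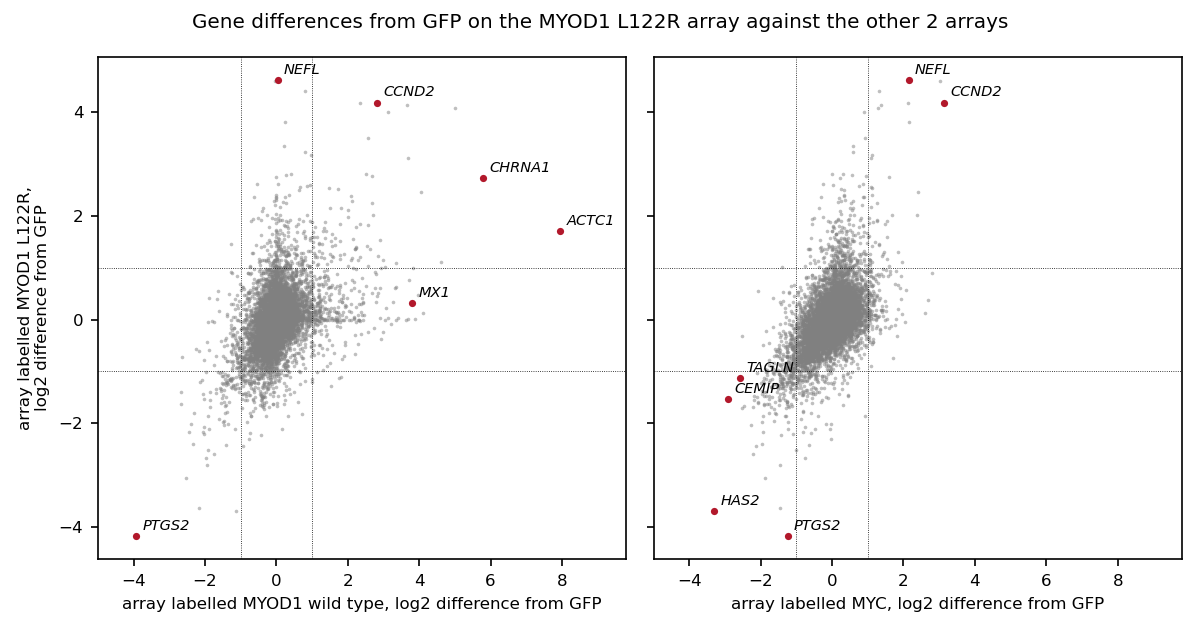
Log2 difference from GFP on the array labelled MYOD1 L122R (vertical axis) against that on the arrays labelled MYOD1 wild type (left) and MYC (right), 1 point per gene, with dotted lines at 2-fold and some named genes in red. The correlations across genes are 0.44 and 0.56. Simulated unchanged arrays give 0.50 from sharing the GFP array alone, so that value does not gauge resemblance.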

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

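The explanations in this part and the tests of them were chosen after the results they bear on were seen, although most of the processing alternatives and the GFP against parental comparison that they draw on were set before. The first pattern is the interferon response list on the array labelled MYOD1 wild type, with a median of 1.95 above GFP. For retroviral infection and selection in general, the list median of GFP minus parental was −0.37, and 0.0777 without rescaling, at percentile 0 both times. Relative to random lists, the list was thus not raised in the infected and selected GFP culture. This pair is 1 array each, and no label states whether parental met zeocin. It therefore cannot exclude infection or selection as the cause in the wild type culture. Scaling, background, probe set and control array are excluded by a lowest median of 1.69 over all alternatives. A state of this 1 culture that owes nothing to MYOD1 is left open, since there is 1 array of wild type MYOD1, and the array labelled MYOD1 L122R lay below it by a median of −1.81. The difference may therefore belong to wild type MYOD1 or to this culture, and other cultures would be needed to tell which.

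The second pattern is the cell cycle list, lower on the arrays labelled MYOD1 L122R and MYC. Scaling, background, probe set and control array are excluded, since the median nearest to 0 over both arrays and all alternatives was −0.88. Loss of 5′ ends of RNA could contribute on the array labelled MYC, where the ACTB 3′/5′ ratio was 5.37, although its GAPDH ratio of 1.29 lay below that of parental (1.34). On the array labelled MYOD1 L122R the ACTB ratio of 3.98 lay below that of parental (4.34, GFP 3.23), and the list's median difference between GFP and parental was −0.0133, which speaks against this loss as the cause there but rests on 1 control array, so the explanation stays open. No biological explanation was tested.

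The third pattern is the MYC probe set, dimmer on the array labelled MYC than on GFP. An exchange of the arrays labelled MYC and MYOD1 L122R would put the ribosome biogenesis list higher on the latter, if MYC raises that list. Its median for MYOD1 L122R minus MYC was −0.62, at percentile 0 of random lists under every alternative. That argues against an exchange but cannot exclude it, since it rests on 1 array each and on that premise. Against GFP 568 genes were past 2-fold, where GFP and parental differed in 44. That argues against another control culture under the MYC label. It cannot exclude one, since a single pair of control arrays sets the yardstick. That the probe set reads the cells' own transcript and not the introduced copy remains possible: the MYOD1 probe set, too, was near background on the array labelled MYOD1 wild type (0.38 above GFP without the floor), and the position of these probe sets in the genes was not analysed here.

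In data outside the gene comparisons, the 24 probe sets of the poly-A controls, added to RNA before labelling, were higher than on GFP by a median of 0.35 on the array labelled MYOD1 L122R and of 1.03 on the array labelled MYC, against −0.04 on parental. All differences reported here are relative to each array's trimmed mean. Scaling to the poly-A controls would lower every difference of the array labelled MYC from GFP by 1.03. That would put the medians of its MYC target lists (0.50, 0.52 and 0.26) below 0. It would also raise the medians of these lists for MYOD1 L122R minus MYC (−0.62, −0.48 and −0.34) to about 0 or above. The 18 probe sets of the hybridization controls, added after labelling, were instead higher on parental, by 0.78, and by 0.18 and 0.17 on the arrays labelled MYOD1 L122R and MYC, so that scaling to them would raise every difference of GFP from parental by 0.78, the interferon median of −0.37 among them, which would still lie below the 1.95 of the array labelled MYOD1 wild type. Among 13522 probe sets without a single gene name, 46 were at least 2-fold higher and 34 at least 2-fold lower than on GFP on the array labelled MYOD1 wild type, 56 and 32 on the array labelled MYOD1 L122R, and 32 and 35 on the array labelled MYC, where GFP against parental had 3 and 1.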

How the results depend on the processing

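Of 347 called values of genes named by rule 194 passed 2-fold under every alternative, and of 66 list medians outside the central 95% of random lists 34 stayed outside under every alternative. The interferon median on the array labelled MYOD1 wild type ranged from 1.69 to 2.04, and the cell cycle medians from −1.34 to −0.88 (MYOD1 L122R) and from −1.52 to −1.003 (MYC). Of 7968 alternative values of named genes 6450 stayed within the spread between GFP and parental, 1511 moved further and 7 turned the sign of a call. Of 1500 list medians 933 stayed within 1 SD of the random medians, 546 moved further, 19 turned the sign of a median outside the central 95% and 2 moved such a median from 0.00 to below 0; medians inside it that crossed 0 are not listed. Of 84 list medians inside the central 95%, 30 lay outside it under at least 1 alternative. Differences from a gene at the floor are lower limits. Where a value below moved, the cause was not tested. Carry-over medians below are given in the order wild type higher and lower read on L122R, MYC higher and lower read on L122R, MYC higher and lower read on wild type, or are named.

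Without rescaling, counts were 190 higher and 674 lower (L122R against GFP), 73 and 830 (MYC against GFP) and 250 and 4 (GFP against parental). The median of all genes was −0.12 (wild type), −0.23 (L122R), −0.19 (MYC), 0.35 (GFP against parental) and −0.12 (L122R against wild type), where after rescaling it was −0.01, 0.03, 0.07, −0.05 and 0.03. Carry-over medians were 0.27, −0.30, 0.74, −0.33, 0.32 and, reversed, 0.18, and the correlation of L122R and MYC was 0.59. Of list medians outside the central 95%, those that changed sign were, for L122R, myogenic factors −0.12, cell cycle inhibitors −0.12 and interferon −0.0885; for MYC, sarcomere −0.0297 and translation −0.0452; for L122R against wild type, ribosome −0.0485 and nucleotides −0.0107; and for GFP against parental, MYC-repressed 0.35, cell cycle 0.44, matrix 0.15, interferon 0.0777, unfolded protein 0.42 and cholesterol 0.25.

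Quantile normalization gave 29 genes lower in GFP than in parental, carry-over medians of −0.56 (wild type lower on L122R), −0.89 (MYC lower on L122R) and −0.33 (MYC lower on wild type), and a correlation of L122R and MYC of 0.53. Split controls gave correlations of 0.29 (L122R and wild type), 0.39 (L122R and MYC) and 0.0519 (wild type and MYC). With the floor at the 20th percentile the sarcomere median of L122R against MYC was −0.0397.

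By the median of all probe sets, counts were 252 higher and 121 lower (wild type against GFP), 185 and 192 (L122R against GFP) and 102 and 250 (MYC against GFP). They were 169 and 281 (L122R against wild type), 182 and 107 (L122R against MYC) and 16 and 11 (GFP against parental). Carry-over medians were 0.0683 (wild type higher on L122R), 0.36 (MYC higher on L122R) and 0.0728 (MYC higher on wild type). GAS1 was −0.0859 in L122R against MYC and −0.00283 in wild type against GFP, and LOXL2 0.0150 in MYC against GFP. Without shared-sequence probe sets GAS1 had those same values, TAGLN was 0.0365 in MYC against GFP and −0.16 in L122R against MYC, and 8 genes were lower in GFP than in parental. Carry-over medians were then 0.35 and −0.71 (MYC higher and lower on L122R) and −0.00246 and −0.22 (MYC higher, reversed, and lower on wild type), the matrix median of wild type was 0.0584, and the sarcomere median of L122R against MYC was −0.00249.

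With GFP and parental exchanged, carry-over medians were 0.25, −0.81, 0.28, −0.83 and, for MYC higher on wild type, −0.0604, reversed. L122R had medians of −0.0498 for myogenic factors and −0.0916 for interferon, and MYC −0.0202 for sarcomere. Normexp correction gave 1.2e2 genes higher in MYC and 9 lower in GFP than in parental, carry-over medians of −0.44 (wild type lower on L122R), −0.69 (MYC lower on L122R), 0.0935 and −0.13 (MYC higher and lower on wild type), and medians for GFP against parental of 0.0508 for cell cycle and 0.0322 for the unfolded protein list. Local centring gave −0.51 (wild type lower on L122R), −0.83 (MYC lower on L122R) and −0.27 (MYC lower on wild type). These last 2 corrections were chosen after the data were seen.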

Other observations

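Several fixed lists outside the main comparisons of muscle, MYC targets, interferon and cell cycle held single genes with large differences from GFP. In the growth factor and PI3K list KIT, the stem cell factor receptor, was higher on the arrays labelled MYOD1 wild type (2.67) and MYOD1 L122R (2.24), and the kinase subunit PIK3CD on the latter (1.89), while EGFR was −1.97 with wild type at its brightest probe set and under 2-fold by the median of all. The list had 2 genes higher and 3 lower of 35 with wild type (median −0.02, but −0.06 and percentile 1.99 by the median of all probe sets), 3 and 2 with L122R (0.00) and 1 and 1 with MYC (0.07). Targets of p53 had 2 of 21 higher with wild type, TP53I3 (1.20) and PLK2 (1.13, under 2-fold without rescaling), with a median of 0.27 (percentile 99.99), 2 with L122R (median 0.06, percentile 90.1, but 0.35 and percentile 99.94 against parental) and 1 with MYC (median 0.30, percentile 99.9), and 0 lower on each. The wild type median of this list was inside the random range for some choices of probe sets. The cell cycle inhibitors with D cyclins had 4 higher and 0 lower of 17 with wild type (median 0.28, percentile 99.97), 3 and 0 with L122R (median 0.17, percentile 98.8, inside the random range against parental) and 4 and 1 with MYC (median 0.12, percentile 90.2), where CDKN2A, the inhibitor of CDK4 and CDK6, was 1.32 and CDKN1B −1.10. The wild type median was inside the random range in 4 of 11 alternatives, and its 4 higher genes, CCND2, CCND3, CDK6 and CDKN1C, were under 2-fold by the median of all probe sets. So were CCND2, CDK6 and CDKN1C with L122R, and CCND2, CDK6 and CDKN2B with MYC. In the unfolded protein and ATF4 list DDIT4, an inhibitor of mTOR signalling, was higher with MYC (1.96), and L122R had 2 higher and 3 lower of 32 (median −0.21, percentile 1.90, inside the random range by the median of all probe sets), against 1 and 1 with wild type (median 0.02) and 1 and 0 with MYC (median −0.09). Glycolysis genes had 1 higher, the pyruvate kinase PKM (1.06, under 2-fold by the median of all probe sets), and 1 lower of 19 with wild type (median −0.00, but −0.17 and percentile 0.51 against parental), 2 and 0 with L122R (−0.10) and 1 and 0 with MYC (−0.03), where GPI was 1.09 (under 2-fold without rescaling). Cholesterol synthesis genes had 0 of 18 past 2-fold with wild type (median 0.07) and with MYC (median −0.06), but against parental these medians were −0.19 (percentile 1.72) and −0.25 (percentile 0.36).

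Markers of other cell types held few calls. Epithelial genes had 0 higher of 14 on each array and 2, 2 and 1 lower with wild type, L122R and MYC (medians 0.00, 0.01 and 0.12, but −0.23 with wild type against parental and −0.32 with L122R and the floor at the 60th percentile, both outside the random range), with the keratin KRT18 at −2.11 with L122R. Endothelial genes had 0 of 11 past 2-fold on each (medians 0.00, 0.00 and 0.13). Haematopoietic genes had 1 of 15 past 2-fold, the actin-bundling LCP1 (1.05) with L122R (medians 0.00, 0.00 and 0.09). Neural genes had 0 of 17 past 2-fold with wild type, 2 higher and 1 lower with L122R and 1 and 1 with MYC (medians 0.03, 0.00 and 0.17), NEFL higher and the tubulin TUBB3 lower on both (−1.23 and −1.25). Adipocyte, cartilage and bone genes had 1 of 16 higher, SOX9 (1.01) with L122R, which like LCP1 was under 2-fold in several alternatives (medians 0.00, 0.04 and 0.06).

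One hypothesis was that the genes lower on the array labelled MYC were lower on the array labelled MYOD1 L122R only because both hold lower cell cycle genes. Its prediction was written before the test was run. Of the 374 genes lower with MYC, 32 belong to the cell cycle list, and the 342 others had a median of −0.71 for L122R against parental (percentile 0), with 106 at least 2-fold lower. With so few genes left out the median could not have reached the random range: without as many of the lowest genes it would be −0.702. The test therefore decides nothing, and the hypothesis stays open.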
